A study of Mus musculus with 14 samples.

How the data were processed

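The series holds 14 hybridisations of spotted cDNA arrays with 2 colours. Per the labels, 20 µg of total RNA of a mutant organ was labelled with Cy3 or Cy5 and mixed with a pool of control RNA labelled with the other dye. The deposited scanner files give, per the file headers, foreground and local background intensity of each spot in a red and a green scan, read here as Cy5 and Cy3. They hold 20205 spots for 20160 probes and are not normalised. The scanner, its software and their versions are not given in the sources used here. The authors' value table was compared with the scanner values: by column, 99.7% to 99.9% of comparable rows equal the log2 ratio of background-subtracted foreground medians plus 1 constant, within 0.01. Its ratios run from mutant over pool, per the labels' dyes. Its columns are not centred, with medians from -1.38 (thymus replicate 2) to 0.865 (thymus replicate 3), and the origin of the added constants stays unknown. It was used only as an alternative.

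The labels disagree in 3 places. Thymus replicate 1 carries the tissue brain in 1 characteristic, while its title and its pool name thymus, and it was analysed as thymus. The control pools list 4 animals, while the labelling protocol speaks of 6. Mouse identifiers of mice 3 and 4 differ by exchanged digits between labels and file names, and the labels were used.

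Foreground means were corrected with normexp (offset 50) and normalised within each array by loess (span 0.3), with flagged spots (flag -50) given weight 0 and left out, in limma 3.58.1 with statmod 1.5.0 under R 4.3.3. Flagged spots made up 0.812% to 10.7% of spots on brain arrays and 9.32% to 72.4% on thymus arrays. Every ratio was turned to mutant over pool, spots of a probe were averaged, and the dye-swapped arrays of a mouse were averaged to 1 value, for which both arrays had to give a value. A probe was detected on an array where its foreground lay at least 2 background SDs above the background median in at least 1 channel. A probe was tested in an organ where it was detected on a share of at least 0.5 of the arrays and at least 2 mice gave a value. No arrays held identical values. The offset pulls ratios of dim spots toward 0.

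Probes were named by RefSeq accession without version (961 probes) or by a synonym of a single gene (490 probes) in a RefSeq table of GRCm38.p6, from which no coordinates were used. Of 933 RefSeq mRNA accessions on the array, 904 matched. Of the spots, 6312 carry no accession.

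For each organ the mouse values were tested against 0 with limma's moderated test (lmFit and eBayes) and Benjamini-Hochberg adjustment over all tested probes, at an adjusted p of 0.05. The replicate is the mouse, and the pool counts as 1 control sample, so the spread among controls is left out. Without borrowing spread across probes, sign flips of 3 and 4 mice could give no two-sided p below 0.25 and 0.125. The difference between organs was tested on the 7 mouse values without a block. Mice 1 to 3 gave both organs, so their numbers pair the samples by animal. Their deviations from the organ means correlated at -0.00292, -0.00385 and -0.0111 across probes, against a mean of 0.00306 for unequal numbers.

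Gene lists, 36 in number, were fixed before the data were examined, and lists with at least 5 tested genes were tested with limma's camera on moderated statistics at a preset correlation of 0.01, 1 probe per gene (the brightest). The remaining lists with tested genes are described by members, and some members are not reported here. The lists of choroid plexus, erythroid and interferon genes had no named probe on the array. The named genes follow a rule fixed at the same time: genes past the threshold with a single sign in all mice and dye orientations, and, as fewer than 20 passed, those of smallest p that met the sign rule, as values. Of each list, up to 4 members past the threshold or else the 2 of smallest p were taken as values, and for the difference between organs the 10 smallest p, of which the first 2 are printed. Spot intensities of the organs were compared after quantile normalisation of the mean log2 intensity of both channels, with limma, a step chosen after seeing the data, as was the check of each thymus array on probes selected without its mouse.

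The procedure was tested on simulated data by multiplying the signal above background of 200 seeded probes in the mutant channel by known factors. No unaltered probe was called in any of these runs. The unaltered probes are the real data, in which none passed, so this 0 says little about false calls. For lists of 6 genes, 20 of 20 shifted by 0.2 and 1 of 20 not shifted were called with the preset correlation. Their members were drawn at random, so lists of genes that vary together were not simulated.

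Alternatives covered background correction, foreground median, print-tip loess, median centring, scaling between arrays, the filter on dim probes, flagged spots, the authors' table, each dye orientation alone, each mouse left out, arrays as units with and without the mouse as a block, the variance model, a joint fit, thresholds, blocks for the mouse, and other list tests. The files used give no slide or scan batch, so none was tested. A search for microRNA seed matches needs 3' UTR sequences, which were not used here.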

Results

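The series measured gene expression in brain and thymus of male mice without miR-34a, a microRNA that is transcribed under the control of p53 and represses many mRNAs of the cell cycle and of cell survival. The mutants had the C57BL/6 background and an age of 17 weeks. Brain RNA came from 3 mutants and thymus RNA from 4 mutants, 3 of which also gave the brains. Each mutant RNA was hybridised on 2 spotted cDNA arrays with the dyes exchanged, which gave 6 arrays of brain and 8 of thymus. The other channel of each array held a pool of control RNA of the same organ, so each array gave a ratio of mutant over pool. No control mouse was hybridised alone, and every test of a ratio below sets the mutants against 1 pool per organ and leaves out the spread among controls.

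Signals were low in both organs, with ranges that overlapped. The median spot lay 1.45 to 2.36 times above its background in Cy5 on the brain arrays and 1.10 to 1.70 times on the thymus arrays. In Cy3 it lay 1.81 to 2.25 times above background in brain and 1.21 to 2.67 times in thymus, where replicate 6 exceeded every brain array. Between 56.2% and 94.4% of probes were detected on single brain arrays, against 7.75% to 84.9% on single thymus arrays. The extremes in thymus were replicate 8 with 7.75% and replicate 6 with 84.9%. The number of mice, 3 for brain and 4 for thymus, limits the precision of all values. Gene symbols were available for 1451 of 20160 probes, which stood for 1378 genes, and no probe carried the name Mir34a, so the loss of the microRNA itself was not measured.

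Single marker genes differed between the organs, in a comparison of spot intensities that was chosen after seeing the data. Satb1, a chromatin organiser of developing T cells, had a log2 intensity of 8.42 ± 0.46 (SD, n = 4 mice) in the thymus hybridisations and 6.73 ± 0.04 (SD, n = 3) in those of brain, with a limma adjusted p = 0.00861. Cd8a, the T cell coreceptor, stood at 7.25 ± 0.28 in thymus and 6.17 ± 0.21 in brain (SD, n = 4 and 3, limma adjusted p = 0.0215). Stmn2, a tubulin-binding protein of neurons, stood at 8.47 ± 0.30 in brain and 6.85 ± 0.09 in thymus (SD, n = 3 and 4, limma adjusted p = 0.00276). The Stmn2 values here are of its brighter probe. The dimmer probe, at 7.36 ± 0.43 in brain and 6.64 ± 0.10 in thymus, did not pass (limma adjusted p = 0.103). Thymus replicate 1, for which 1 of the labels names the other organ, gave 8.72 for Satb1, 7.78 for Cd8a and 6.95 for Stmn2, on the side of thymus for all 3 genes. These genes were picked for their difference and replicate 1 is part of the thymus means, so probes were also chosen without its mouse: of 128 probes past the threshold between brain and the other 3 thymus mice, replicate 1 lay nearer the thymus mean for 124 and nearer the brain mean for 4. The other thymus arrays, with the same rule, lay nearer thymus for 83.1% to 95.9% of probes, except replicate 6 with 58.6%. Replicate 6 lay nearer thymus for only 15 of the 92 probes that were higher there, but for 132 of the 159 higher in brain. The thymocyte marker Cd4 did not separate the organs (6.94 ± 0.10 in thymus, SD, n = 4, and 6.80 ± 0.19 in brain, SD, n = 3), and replicate 1 gave 6.12 for it. Whole intensity profiles separated the organs little: replicate 1 correlated at a mean of 0.465 with the other thymus arrays and 0.438 with brain arrays, replicate 6 at 0.374 and 0.425, and replicate 8 at 0.463 and 0.481.

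**Figure D1:**
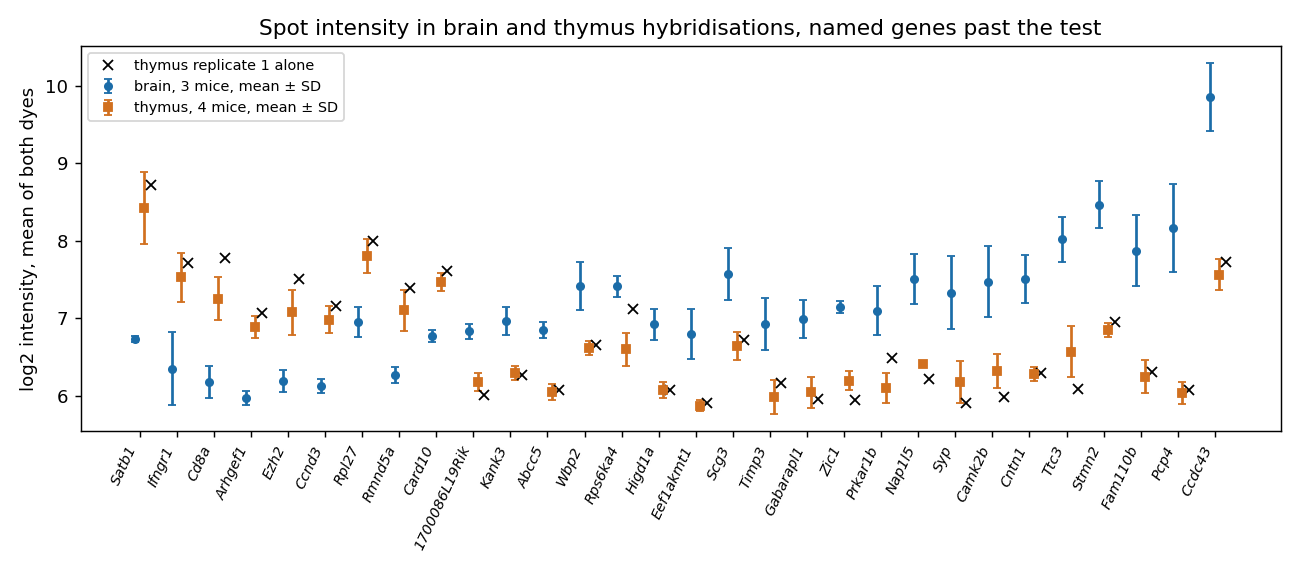
Log2 spot intensity (mean of both dyes, quantile-normalised) of the named genes with the lowest and highest brain minus thymus differences past an adjusted p of 0.05, as mean ± SD over 3 brain and 4 thymus mice, with thymus replicate 1 as a cross. Satb1 stood at 8.42 in thymus and 6.73 in brain, and replicate 1 gave 8.72.

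The first comparison asked which transcripts differed in brain between mutants and the control pool. No probe did: 0 of 17586 tested probes passed an adjusted p of 0.05 in the moderated test of limma, with a smallest adjusted p of 0.846. At an unadjusted p under 0.05 there were 785 probes, where a uniform distribution of p would give 879.3. Flipping the signs of whole mice gave 372 to 568 such probes in the 3 other sign patterns, too few patterns for a test. The median 95% confidence interval reached 0.16 on the log2 scale to either side of the estimate, and 97.1% of the intervals lay within a 1.5-fold change. These log2 ratios understate changes of dim spots: known 2-fold changes put into the brain scanner values of 67 of the 200 altered probes came back with a median log2 ratio of 0.79. In that simulation 28.4% of the 1.5-fold, 62.7% of the 2-fold and 80.3% of the 4-fold changes passed the adjusted threshold among 17581 fitted probes. The 200 probes were altered together and by equal factors in every mouse, and many joint calls loosen the Benjamini-Hochberg cutoff. These shares may therefore overstate the power for few changes, or for changes that vary between mice.

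Among named genes of brain, 11 had the same sign on all 6 arrays, and none passed the adjusted threshold in limma (adjusted p = 0.846 for each). Of all probes measured on every brain array, 224 of 15608, or 1.44%, had a single sign on all 6 arrays, below the 3.12% that random signs give. The lowest of the 11 was Cep295nl, at a log2 ratio of -0.34 ± 0.40 (SD, n = 3), and next came Rilpl1, a regulator of ciliary protein traffic, at -0.23 ± 0.14. Acan, the core protein of the proteoglycan aggrecan, stood at -0.11 ± 0.04 (SD, n = 3). The highest were Ergic1, a protein of transport between endoplasmic reticulum and Golgi, at 0.18 ± 0.11, and Fkbp3, a peptidyl-prolyl isomerase of the nucleus, at 0.17 ± 0.02 (SD, n = 3 each). Ddx5, an RNA helicase, stood at 0.12 ± 0.02 and Tppp, a tubulin-binding protein of oligodendrocytes, at 0.13 ± 0.10. The others were Zdhhc5 at 0.14 ± 0.07, Rhod at 0.14 ± 0.07, Slc37a4 at 0.12 ± 0.15 and Ttc41 at 0.08 ± 0.06 (SD, n = 3 each).

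Published targets of miR-34a were represented in brain by 7 tested genes of the 50 on that list, with 5 ratios above and 2 below 0. None passed the threshold, adjusted over the list alone or over all probes. Efnb1, an ephrin ligand, stood at 0.17 ± 0.17 and Ldha, lactate dehydrogenase A, at 0.13 ± 0.11 (SD, n = 3 each). Klf4, also on this list but outside its naming rule, stood at -0.12 ± 0.09 (SD, n = 3), similar to Ldha in size and opposite in sign. The list as a whole had a mean log2 ratio of 0.04, with a camera adjusted p = 0.364, and adjusted p = 0.553 with an estimated correlation. Genes next to Mir34a on the chromosome had 7 tested members, 5 above and 2 below 0, with a mean of 0.07 and a camera adjusted p = 0.0994 (adjusted p = 0.380 with an estimated correlation). Ctnnbip1, an inhibitor of beta-catenin signalling, had the highest ratio among them, 0.27 ± 0.14 (SD, n = 3), above 0 in 3 of 3 mice. Its limma adjusted p over the list alone was 0.0530. Park7 stood at 0.09 ± 0.03 (SD, n = 3).

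Ribosomal protein genes and genes of synaptic vesicles were higher than the other probes of brain as groups, in 2 of the 5 lists that had at least 5 tested genes. Against random lists matched on intensity, their medians lay at the 95.6 and 97.0 percentile, under the bound set beforehand. The 6 ribosomal genes had a mean log2 ratio of 0.11, all 6 above 0, with a camera adjusted p = 0.0110 at a preset correlation of 0.01, and no call at an estimated correlation (adjusted p = 0.288). The 6 synaptic vesicle genes had a mean of 0.08, all 6 above 0, with an adjusted p = 0.0191 at the preset and 0.288 at the estimated correlation. With the estimated correlation, 0 of 20 simulated lists of 6 genes shifted by 0.2 were called, against 12 with fry and 20 with the preset. The simulated members were random probes that need not vary together, and 0.2 exceeds both means, so this decides nothing between the settings. No single member passed the threshold, adjusted over the list alone or over all probes. Rpl6 stood at 0.20 ± 0.21 and Rpl30 at 0.10 ± 0.09. Nsf, the ATPase that recycles SNARE complexes, stood at 0.13 ± 0.03, and Syp, synaptophysin of the vesicle membrane, at 0.13 ± 0.05 (SD, n = 3 each). In spot intensity, the synaptic members Slc17a7 (7.37 in brain, 7.71 in thymus), Syn1 (6.33 and 6.99) and Syngr1 (6.35 and 6.41) were not higher in brain. Nsf, Syt1 and Syp stood higher in brain, and only Syp passed the threshold (limma adjusted p = 0.0391). Whether the probes of Slc17a7, Syn1 and Syngr1 report synaptic transcripts was not tested. With the mutant in Cy3 only, the synaptic list had a mean of -0.04 and the ribosomal list one of 0.0011, and neither was called. Without mouse 1 the list means were 0.09 for the ribosomal and 0.08 for the synaptic list (adjusted p = 0.126 for each), and without mouse 3 they were 0.11 and 0.08 (adjusted p = 0.0530 and 0.0709), so these calls ended with little change of the means. Only the synaptic list passed with fry (adjusted p = 0.165 for the ribosomal list), and only the ribosomal list with print-tip loess and without the filter on dim probes (adjusted p = 0.0552 and 0.104 for the synaptic list).

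**Figure D2:**
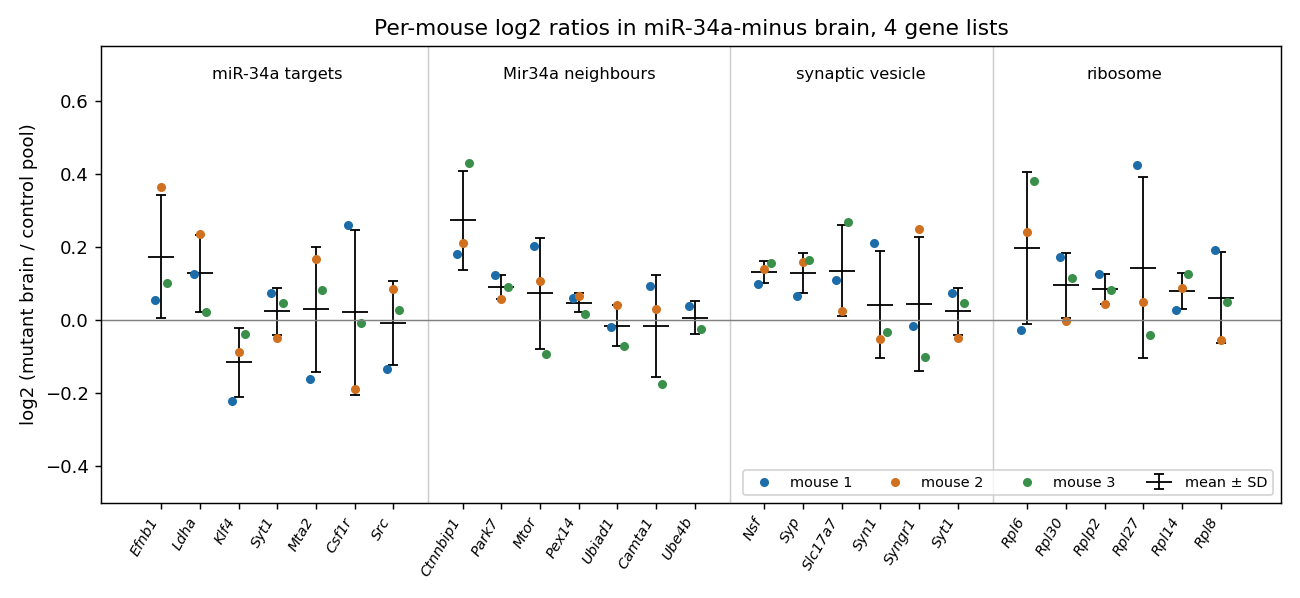
Log2 ratio of mutant brain over control pool for the tested genes of 4 lists, with 1 point per mouse (mean of its dye-swapped arrays) and a bar for mean ± SD over 3 mice (2 for Ube4b). All 6 means of the ribosomal and all 6 of the synaptic vesicle genes lie above 0.

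Markers of cell types and of other pathways gave no call in brain. The muscle list, with 7 tested genes, had a mean of -0.03 and a camera adjusted p = 0.364, and its lowest member Tcap, a sarcomere protein, stood at -0.18 ± 0.19 (SD, n = 3). That value is from the brighter of the Tcap probes, and with the mean over all probes of each gene the list mean was -0.0126. Neuron markers had 4 tested genes, 3 above and 1 below 0: Slc17a7, the vesicular glutamate transporter, stood at 0.13 ± 0.12, Stmn2 at 0.10 ± 0.06, and, outside the naming rule, Syt1 at 0.02 ± 0.06 and Camk2b at -0.09 ± 0.09 (SD, n = 3 each). Slc1a6, the glutamate transporter of Purkinje cells, stood at 0.14 ± 0.05 and the other cerebellar marker Zic1 at -0.01 ± 0.07, and of oligodendrocyte transcription factors Olig1 stood at 0.09 ± 0.18 and Olig2 at -0.01 ± 0.20 (SD, n = 3 each). The astrocyte marker Ntsr2 stood at 0.13 ± 0.19, the microglial C1qa at 0.09 ± 0.20 and the endothelial Eng at -0.14 ± 0.12. Among apoptosis regulators Mcl1, an anti-apoptotic protein, stood at -0.11 ± 0.01 and Birc2 at 0.11 ± 0.04 (SD, n = 3 each). Of p53 targets Perp stood at -0.14 ± 0.16, and of cell cycle genes Cdt1, a factor of replication licensing, at -0.10 ± 0.09. Only Hsp90b1, a chaperone of the endoplasmic reticulum, passed adjusted over the list alone, in a list of 2 tested genes (limma adjusted p = 0.0411 there and 0.846 over all probes). It stood at 0.18 ± 0.07 (SD, n = 3), above 0 in 3 of 3 mice, and at -0.03 with the mutant in Cy3 only.

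The remaining lists of brain had 0 to 4 tested genes each (4 of the 36 lists had none), and none of their tested members passed the threshold, adjusted over the list alone or over all probes. Of Notch pathway genes the receptor Notch3 stood at -0.07 ± 0.09 and the protease Adam10 at 0.05 ± 0.09, with 2 of 3 above 0. Of the Sonic hedgehog list, the antagonist Hhip stood at 0.10 ± 0.08 and Gas1 at -0.11 ± 0.16, with 1 of 4 above 0. Of stress and hormone responses, the glucocorticoid-induced Tsc22d1 stood at 0.18 ± 0.16 and Nfkbia at -0.09 ± 0.15, the immediate early genes Klf4 at -0.12 ± 0.09 and Jun at 0.09 ± 0.11, and the clock genes Dbp at -0.03 ± 0.18 and Per2 at 0.0044 ± 0.0587 (SD, n = 3 each). Region markers of striatum and pituitary were Drd2 at 0.11 ± 0.33, Tac1 at -0.05 ± 0.09 and Tshb at 0.06 ± 0.17. Of metabolic lists, Cyp51 of sterol synthesis stood at 0.09 ± 0.12, Scd2 at 0.06 ± 0.13, the respiratory chain gene Atp5a1 at 0.01 ± 0.05 and the proteasome gene Psmd14 at 0.07 ± 0.08. Markers of immune, epithelial, fat and matrix cells were Satb1 at 0.15 ± 0.26, Ccl17 at -0.10 ± 0.03, Mmp8 at -0.11 ± 0.05, Cxcl12 at -0.10 ± 0.15, Lpl at -0.05 ± 0.11 and Mgp at -0.01 ± 0.07 (SD, n = 3 each).

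The same question was put to thymus. No probe differed from the control pool: 0 of 5321 tested probes passed the adjusted threshold in limma, the smallest adjusted p was 0.853, and 267 probes had an unadjusted p under 0.05 where a uniform distribution of p would give 266.05. The 7 other sign patterns of the mice gave 158 to 269. The median 95% confidence interval reached 0.23 on the log2 scale to either side, and 93.9% of the intervals lay within a 1.5-fold change. All 4 mice gave a value for 1813 of these probes. Known 1.5-fold, 2-fold and 4-fold changes put into the thymus scanner values passed in 16.4%, 38.8% and 59.1% of cases among 5284 fitted probes, and the 2-fold changes came back with a median log2 ratio of 0.55. As in brain, the probes were altered together and equally in every mouse, so these shares may overstate the power for few changes.

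Named genes with the same sign on all 8 thymus arrays numbered 5, all with an adjusted p of 0.853 in limma. Ccdc43 stood at 0.20 ± 0.05, Fcgr2b, the inhibitory Fc receptor, at 0.16 ± 0.04, and Satb1 at 0.09 ± 0.04 (SD, n = 4 each). Sncb, a synuclein, stood at -0.19 ± 0.16 and Adcy6, an adenylate cyclase, at -0.10 ± 0.06 (SD, n = 4 each). Among probes measured on all 8 arrays, 22 of 1813 or 1.21% had a single sign, against 0.781% by chance.

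Gene lists were thinly covered in thymus, and only the ribosomal list had 5 or more tested genes. Its 6 genes had a mean log2 ratio of 0.02, 4 above and 2 below 0, with a camera adjusted p = 0.498 and adjusted p = 0.860 with an estimated correlation. Each dye orientation alone gave a call in the opposite direction, with a mean of -0.09 with the mutant in Cy3 (adjusted p = 0.0382) and 0.13 with the mutant in Cy5 (adjusted p = 0.00944). Thymocyte markers had 4 tested genes, none past the threshold, with Cd4 at 0.15 ± 0.03 (SD, n = 3). The miR-34a targets had 3 tested genes, 1 above and 2 below 0: Mta2 stood at 0.77 ± 1.19 and Csf1r at -0.17 ± 0.05 (SD, n = 2 each), and Ldha was not past the threshold either. Of apoptosis regulators, Bak1, a pore-forming protein of mitochondria, stood at 0.27 ± 0.10 (SD, n = 2). Epcam, an adhesion protein of thymic epithelium, stood at 0.37 in both mice that gave a value. It passed adjusted over the list alone, in a list of 2 tested genes (limma adjusted p = 0.0259 there and 0.853 over all probes).

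Other lists of thymus had 0 to 3 tested genes each (14 of the 36 lists had none, p53 targets and mature T cell markers among them), with no tested member past the threshold, adjusted over the list alone or over all probes. Adam10 stood at 0.10 ± 0.08, Gmnn, an inhibitor of replication licensing, at 0.06 ± 0.02 and Nfkbia at -0.13 ± 0.13 (SD, n = 4 each). Hsp90b1 stood at -0.03 ± 0.19, Mgp, a matrix protein, at 0.14 ± 0.16 and Atp5a1 at -0.13 ± 0.27 (SD, n = 4 each). The macrophage marker C1qa stood at 0.07 ± 0.09, the muscle gene Tnnt3 at -0.14 ± 0.07 and Scd2 at -0.14 ± 0.24 (SD, n = 3 each). Of the neuronal genes on the array, Slc17a7 stood at -0.07 ± 0.10 and Stmn2 at 0.08 ± 0.22 (SD, n = 4 each), and the only tested neighbour of Mir34a, Pex14, at 0.07 ± 0.10 (SD, n = 2).

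Brain and thymus were then compared for the change itself. None of the 5160 probes tested in both organs differed in its ratio between them by limma (0 past the adjusted threshold, smallest adjusted p of 0.692), with 355 probes at an unadjusted p under 0.05 where a uniform distribution of p would give 258. In the simulation, 21.4% of 14 brain changes of 1.5-fold, 66.7% of 15 of 2-fold and 61.9% of 21 of 4-fold passed this test. Here too the changes were made together and equal in every mouse, so these shares may overstate the power. The smallest p belonged to the unnamed probe with accession BE381430, at -0.21 ± 0.12 in brain (SD, n = 3) and 0.22 ± 0.05 in thymus (SD, n = 4). The next was BE950370, at -0.03 ± 0.03 in brain and 0.43 ± 0.07 in thymus (SD, n = 3 each). Of named genes, Ccdc43 had the smallest p, outside the naming rule for this comparison, at -0.12 ± 0.09 in brain and 0.20 ± 0.05 in thymus. The mean changes of the organs had a correlation of -0.0247 across these probes, which are not independent replicates, and 47.7% had the same direction in both. The sign of this correlation depends on the processing: it changed in 5 of 16 alternatives, which ran from -0.638 with the strict filter on dim probes to 0.133 with median centring.

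Agreement between arrays was low in both organs. Across probes, the mean ratios of different mice correlated at 0.00225 to 0.0600 in brain and at -0.0665 to 0.0749 in thymus. The dye-swapped arrays of a mouse correlated negatively once both were turned to mutant over pool, at a mean r of -0.293 over 3 brain pairs and -0.0948 over 4 thymus pairs. Arrays of different mice with the mutant in the same dye correlated positively, at a mean of 0.144 in brain and 0.0886 in thymus. Averaging the dye-swapped pair removes a constant dye effect from the ratios reported above.

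**Figure D3:**
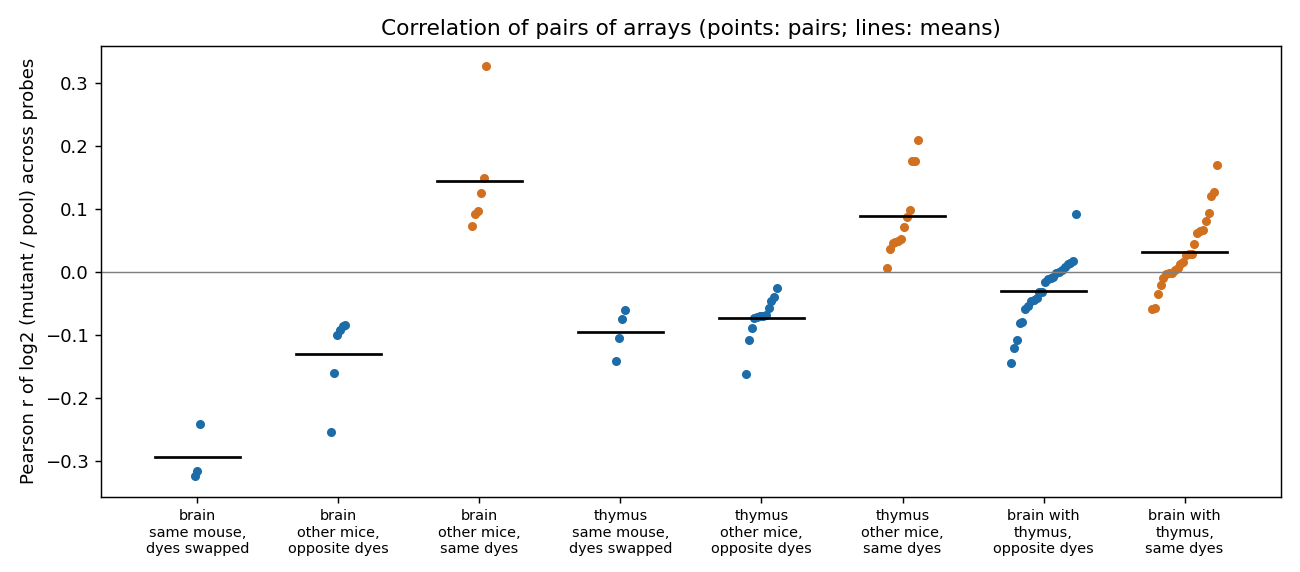
Pearson correlation across probes of log2 mutant over pool for every pair of the 14 arrays, grouped by organ, mouse and dye orientation, with 1 point per pair and a line at each mean. Pairs with opposite dyes lie mostly below 0 (mean -0.293 for swapped arrays of a brain) and pairs with the same dyes mostly above 0 (mean 0.144 for brain).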

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

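Every test of the dye-swap pattern weighed here was chosen after the result was seen, except the one on print blocks over all 7 pairs. Of 23 sets of values screened (8 array measures and 15 thymus genes with 4 mice), 2 held a sample far from the others by Dixon's outlier rule. Its nominal chance rate of about 1 in 20 was not checked on these data. The median spot of thymus replicate 6 lay 2.67 times above background in Cy3, against 1.21 to 1.68 on the other 7 thymus arrays. Atp5a1, a subunit of mitochondrial ATP synthase, had a log2 ratio of -0.53 in thymus of mouse 4, against -0.03 to 0.05 in the other 3 mice. Mouse 4 includes thymus replicate 8, the array with 7.75% of probes detected.

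The dye-swapped arrays of each of the 7 mouse and organ combinations correlated negatively in mutant over pool. Offsets and intensity trends of single print blocks do not account for all of it in brain. The mean r of the 3 brain pairs was -0.196 (SE 0.0337) after print-tip loess, against -0.293 with loess over the whole array. Print-tip loess fits the ratio on intensity per block and does not use position inside a block, which was not tested. For the 4 thymus pairs the mean r was -0.0620 (SE 0.0246) after print-tip loess, against -0.0948. Block effects stay open there, as they do over all 7 pairs (-0.119 against -0.180). A probe-specific dye bias is a candidate explanation for part of it: in Cy5 over Cy3, brain and thymus arrays with opposite orientation correlated at a mean of 0.0304 (SE 0.0105 over 24 pairs that share arrays), about the same as those with the same orientation (0.0324). In the same measure, swapped arrays of a brain correlated at 0.293, but opposite-dye arrays of different brains at 0.129 (0.0948 and 0.0730 in thymus). A bias common to all arrays would not by itself give the gap in brain, and its cause was not tested. A genotype effect with wrongly recorded dyes cannot be told apart from a dye bias, since no probe of known response checks the dyes. Taking the dyes as not swapped gave 2 probes past the threshold in brain (BE953442 and AI851586) and 0 in thymus.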

How the results depend on the processing

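The choices were made before the data were examined, except the centred authors' table and the dyes taken as not swapped. The counts of 0 were kept in 19 of 23 alternatives for brain, 23 of 24 for thymus and 21 of 23 for the difference, and the cause of the exceptions was not tested. Among these, the threshold of 0.1 and the added bound of 1.5-fold reuse the fits of the main analysis. With smallest adjusted p in limma of 0.846, 0.853 and 0.692 there, they could give only 0 and add no evidence. Brain gave 1 probe with foreground medians (MG-3-50n9), 1 with the mutant in Cy5 only (BE953442), 2 with dyes taken as not swapped, and 0 to 1 without each mouse (BF462411 without mouse 2). Thymus gave 0 to 1 without each mouse (BC007480 without mouse 2). The difference gave 1 with foreground medians (MG-3-50n9) and 1 with the authors' table (AW457762). Unadjusted counts ran from 147 to 2298 in brain, 10 to 788 in thymus and 17 to 688 for the difference, the lowest with the strict filter, which tested 1070, 125 and 99 probes. As shares these lowest counts exceed those of the main analysis (785 of 17586, 267 of 5321 and 355 of 5160). Probes are not independent, and this excess was not tested.

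With the mouse as a random replicate block the difference gave 0 probes (342 at an unadjusted p under 0.05), and with the replicate block on the 3 shared mice 0 (238), so pairing changed no call.

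The 2 lists shifted in brain became 3 with background subtracted, where the neighbours of Mir34a passed too (adjusted p = 0.0475, and 0.0475 to 0.976 over 18 alternatives), 1 with print-tip loess, 1 without the filter on dim probes, 1 with fry, 0 with an estimated correlation, 0 with the mutant in Cy3 only, where the synaptic list turned to -0.0436, and 0 to 2 without each mouse (0 without mouse 1 or mouse 3). Adjusted p over 18 alternatives ran from 0.00011 to 0.663 for the ribosomal and from 6.87e-05 to 0.663 for the synaptic list. In thymus the ribosomal list, not called in the main analysis (mean 0.0218), passed upward with median centring (0.177, adjusted p = 0.00961) and with the mutant in Cy5 only (0.131, adjusted p = 0.00944), and downward with the mutant in Cy3 only (-0.0873, adjusted p = 0.0382).

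The correlation between organs was -0.0636 with foreground medians, -0.0458 with print-tip loess, 0.133 with median centring, -0.00197 without the filter, -0.638 with the strict filter, 0.00327 with flagged spots kept, 0.12 with the authors' table, 0.0389 with the mutant in Cy3 only and 0.101 in Cy5 only.

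Of the named genes, 91.4% of 1366 comparisons in brain and 86.5% of 748 in thymus kept their sign, and none passed the threshold. Part of these shares was fixed beforehand, so they do not measure robustness. Genes named for a single sign on all arrays keep it in each dye orientation and without any mouse. Several alternatives, such as the variance model and the filters on dim probes, reuse the same mouse values. With the strict filter no list had 5 tested genes, and batch blocks were not run because the files used give no batch. Thymus had fewer tested probes than brain also without the filter on dim probes (8690 against 18918), and no test separated the causes.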

Other observations

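The comparison of organ levels, the tests of single mice and of a constant dye bias for the lists of brain, and all tests of the brightest probes were chosen after the result was seen. Spot intensities, which hold mutant and control RNA together, differed between the organs for 329 of 18127 probes by limma, 239 higher in brain and 90 in thymus, and 32 of them had gene names. Among named genes past the threshold, Ccdc43 stood at 9.85 ± 0.44 in brain (SD, n = 3) and 7.56 ± 0.20 in thymus (SD, n = 4), with an adjusted p = 0.00169. Pcp4, a calmodulin regulator of Purkinje cells, stood at 8.16 ± 0.57 in brain (SD, n = 3) and 6.04 ± 0.14 in thymus (SD, n = 4) on the log2 scale (adjusted p = 0.00380). Cntn1, a neuronal adhesion protein, stood at 7.50 ± 0.31 and 6.28 ± 0.09 (adjusted p = 0.00861), Syp at 7.33 ± 0.47 and 6.18 ± 0.27 (adjusted p = 0.0391), Camk2b, a subunit of a calcium-dependent kinase, at 7.47 ± 0.46 and 6.32 ± 0.22 (adjusted p = 0.0343), and Zic1, a transcription factor of cerebellar granule neurons, at 7.15 ± 0.08 and 6.19 ± 0.12 (adjusted p = 0.00971). Pcp4 was detected on 0, Cntn1, Syp and Zic1 on 1 and Camk2b on 2 of the 8 thymus arrays, so their thymus levels may lie at the floor and their differences are not ranked.

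On the thymus side, Ezh2, the histone methyltransferase, stood at 7.08 ± 0.29 in thymus (SD, n = 4) and 6.19 ± 0.14 in brain (SD, n = 3) (limma adjusted p = 0.0409). Ccnd3, a D-type cyclin, stood at 6.98 ± 0.17 and 6.13 ± 0.09 (adjusted p = 0.0215), and Ifngr1, a chain of the interferon gamma receptor, at 7.53 ± 0.32 and 6.35 ± 0.47 (adjusted p = 0.0430). Ezh2 was detected on 4 and Ifngr1 and Ccnd3 on 3 of 6 brain arrays. Of fixed lists, neuron markers had 2 of 4 genes higher in brain, Stmn2 among them by the brighter of its probes. Cerebellum markers had 1 of 2 higher in brain, and thymocyte markers 2 of 5 higher in thymus. Astrocyte (2 genes), oligodendrocyte (2), striatum (2), microglia (4) and thymic epithelium markers (4) had 0. The neuronal genes Slc17a7 (7.37 ± 0.16 in brain, 7.71 ± 0.26 in thymus, adjusted p = 0.343) and Syn1 (6.33 ± 0.33 and 6.99 ± 0.28, adjusted p = 0.141) were not higher in brain (SD, n = 3 and 4).

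The higher ribosomal and synaptic vesicle lists in brain were set against 3 kinds of explanation. A single mouse does not account for them, since the lowest mean of a list in any mouse was 0.0600, although leaving out mouse 1 or mouse 3 ended both calls, at list means of 0.0811 to 0.106 with fewer mice. A trend of the ratio with intensity may contribute, since the medians lay at the 95.6 and 97.0 percentile of 10000 random lists matched on intensity, under the bound set beforehand. A constant dye bias does not account for them, since it cancels in the mean of a swapped pair, and both list means over swapped pairs (0.0842 for the synaptic and 0.110 for the ribosomal list) were above 0 in all 3 mice. The orientations alone differed (synaptic mean -0.0436 with the mutant in Cy3, ribosomal mean 0.219 with the mutant in Cy5), as a bias that cancels would make them, so these values decide nothing about the list means. The cancelling holds by construction for a dye bias that is equal on both arrays of a pair, and an unequal one was not tested. An effect of genotype and the make-up of the shared pool also stay open and untested.

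Probes bright enough to be detected in both channels on all 14 arrays numbered 99. Their log2 ratios correlated negatively between the organs, at r = -0.638 across probes, which are not independent. In a wider set, the 516 brightest probes tested in both organs, r was -0.264, and it was -0.00221 over the other 4644. Of the 99 probes, the ratio was below 0 in brain and above 0 in thymus for 45, the other way for 30. It had the same direction for 24, and 0 probes passed the threshold in either organ or for the difference under this filter. Without any 1 mouse r ran from -0.645 to -0.516. The 17 probes of log2 intensity above 11 do not account for it, since r was -0.573 without them. A constant dye bias does not account for it either, since it cancels in the swapped pairs that give this r. A dye bias unequal between the arrays of a pair would not cancel and was not tested. Single orientations, from which a constant bias does not cancel, gave -0.138 in Cy3 and -0.304 in Cy5. Mice of an organ correlated better with each other than across organs by 0.447 (exact one-sided permutation p = 0.0571 over 35 splits, smallest possible 0.0286). The mice correlated at 0.240 to 0.546 (mean 0.434) in brain, at -0.274 to 0.583 (mean 0.0663) in thymus and at a mean of -0.258 across organs. A shift shared by the brains is what a genotype effect and the make-up of the control pool would both give, so these cannot be told apart.

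For the difference between organs, the real split of the 7 mouse values gave 0 probes past the threshold, which all 35 of 35 splits reach by definition, so this count says nothing about chance. The highest other split gave 15. At an unadjusted p under 0.05 the real split gave 355 probes, and the other splits gave 110 to 504. As many as the real split came from 3 of the 35, the real one included.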
